A study of Mus musculus with 4 samples.

How the data were processed

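Gene counts of 4 RNA sequencing libraries from mouse T-helper 2 cells were analysed. The labels put all 4 libraries in a single group, number them as biological replicates 1 to 4 and give no other cell type, treatment or time, so comparisons were made between genes within a library and between libraries. The labels call the assay total RNA sequencing, while the name of the library protocol document speaks of poly(A)-selected RNA. They also name a document on the differentiation of CD4 T cells. The file headers carry a time of 72 h for each library, whose meaning the labels do not give. Sex was not collected, per the labels.

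The deposited values were raw fragment counts per gene, made with featureCounts 1.4.6-p4 from STAR alignments to mm10 with the exons of the GENCODE vM13 annotation, per the file headers. Both mates of a fragment had to map, and read 1 was counted only on the strand of the gene (strand setting 1), per the file headers. The aligner's version is not given in the sources used here. Each file held 50600 genes with their exon coordinates, strand and exonic length, and no normalised value. The planned tests had assumed estimated counts and TPM from another counter. Because the files held whole counts, the count tests were run on them directly and TPM was computed from the counts and the exonic lengths. Gene symbols and biotypes came from GENCODE vM21 by gene identifier without version, and 224 of the 50600 identifiers had none there. Coordinates are those of the files (mm10).

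Strand classes were computed from the coordinates in the files. A gene was said to have opposite-strand exons when at least 1 base of its exons overlapped an exon of a gene on the other strand, found with bedtools 2.31.1. Pairs in which a gene lay with at least 90% of its exonic bases inside the exons of a protein-coding gene on the other strand were compared by counts per base when both genes together had 300 or more counts over replicates 1, 3 and 4.

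Levels were expressed as CPM and TPM with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Helper-subset contrasts were differences of mean log2(TPM + 1) between gene lists within a library. Ratios of gene pairs were taken on log2(TPM + 0.1), and the pooled length-corrected ratio of replicates 1, 3 and 4 carries an exact 95% interval for the counting error. Both were tested by an exact two-sided sign-flip permutation test over the libraries, whose smallest possible p is 0.13 with 4 libraries and 0.25 with 3. Each gene's level was set against 1 TPM with limma 3.58.1 on log2(TPM + 0.1), fitted with an intercept and a trended prior.

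Genes that varied between libraries, and genes that stood apart in a single library against the other 3, were tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3. TMM scaling was used, with a mean count of 10 or more and Benjamini-Hochberg adjustment at 0.05. The standard error (SE) of a log2 fold change was taken from its size and its F value. In the second test the lone library is assumed to vary like the others, and the test compares libraries, not conditions. DESeq2 1.42.0 was the alternative tool. The mean deviation of a list in a library was set against 10000 random lists of the same size matched on expression decile. Shares of counts carry Wilson 95% intervals, and the detection floor is 3 counts. Fragments without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

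The lists, pairs, tests, filters and most of the other settings tried were fixed before the data were examined. The rule for naming genes covered every Th2 list member, the lead genes of the other helper lists, the preset pairs, and up to 4 members of each other list by mean TPM. It also covered list members that were called variable or apart, the 10 nuclear protein-coding genes with the highest TPM, and the 10 most variable genes. The last part took 5 called genes per library with the largest change and the preset sex-linked genes. Results for a few genes that this rule names are not reported here. Other genes are named as chosen after their values were seen. Values without replicate 2, scaling by strand class and tests within a strand class were added where the text says so, apart from leaving out each replicate in turn, which was planned.

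The tests were tested on simulated counts with the libraries' own depths and 100 genes changed at each fold. The rates below hold for the spread between libraries that was simulated, which was not matched here to that of the data. In the data the biological coefficient of variation, a measure of this spread, was 0.276. It was 0.174 in genes with opposite-strand exons and 0.329 in genes without. The rates of detection and of false calls therefore need not hold for these libraries, or alike for both classes. With 4 libraries, 79% of 4-fold changes in replicate 1 were called, 1% in replicate 2, 80% in replicate 3 and 76% in replicate 4, with 32, 2, 29 and 21 false calls among about 6000 genes. Of 2-fold changes, at most 6% were called. Set against the calls rather than the genes tested, the false calls in replicates 1, 3 and 4 exceeded the share that the adjusted threshold allows. With 4 libraries the test of a single library thus did not hold its level in the simulation. Without replicate 2, 92% of 4-fold changes were called in replicate 1, 92% in replicate 3 and 84% in replicate 4. The false calls there were 13, 9 and 4. Set against the calls, those in replicates 1 and 3 again exceeded the share that the adjusted threshold allows, while those in replicate 4 did not. The test of variable genes called 58% of genes changed 4-fold and 100% of those changed 16-fold, with 8 false calls. A gene at 8 TPM was called above 1 TPM in 5% of simulated cases with 4 libraries and in 100% without replicate 2. A list lowered 2-fold in replicate 3 was called without replicate 2 but not with 4 libraries, and a list lowered 4-fold was called in both, with 1 false call among 48 unchanged lists without replicate 2.

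The total counts were 2388255, 5016, 1929880 and 1713199 in replicates 1 to 4, so 3 counts correspond to 1.26, 598.09, 1.55 and 1.75 CPM. Alternatives comprised other pseudocounts, filters and thresholds, DESeq2, stricter lists, medians, and each replicate left out. Strand-specific signal tracks and alignments of these libraries were not used here.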

Results

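RNA from T-helper 2 (Th2) cells was sequenced in 4 libraries. These CD4 T cells make interleukins 4, 5 and 13 and act in responses to helminths and in allergy. The cells were primary cells of the mouse strain C57BL/6NJ and formed a single group of 4 biological replicates. The labels give each replicate its own biosample but the same donor. The X-linked gene Tsix had 3223 counts in replicate 1 against 1 and 3 in replicates 3 and 4, which argues against a single animal behind all libraries. Whether replicates 3 and 4 share an animal is not known. The p-values may thus measure only the spread between these samples, which may be technical in part. Replicate 1 had 2388255 gene counts, replicate 3 had 1929880 and replicate 4 had 1713199, whereas replicate 2 had 5016, which was 341.5-fold less than the lowest of the others. At least 1 count was found for 15516, 2017, 13995 and 14876 genes in replicates 1 to 4. A level below 598.09 CPM was under the 3-count floor in replicate 2, while the floor was 1.26 to 1.75 CPM in the others, so most statements rest on replicates 1, 3 and 4.

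The shares of counts in RNA classes were asked first. Among nuclear protein-coding genes the highest TPM belonged to Gm20721, at 18505 ± 4479 TPM (SD, n = 4), which lies on chromosome 2 at 174330319 to 174346712 (mm10) opposite Gnas, the gene of the stimulatory G-protein alpha subunit. Tlcd1 reached 2980 ± 530.3 TPM opposite Rpl23a, a ribosomal protein gene. Acat3 reached 2813 ± 757.6 TPM opposite Tcp1, a chaperonin subunit gene, and Snx22 reached 2205 ± 411.8 TPM opposite Ppib, a cyclophilin gene. The others of the top 10 were Gm17606, Gm17617, Gm26602, Phykpl opposite Hnrnpab, Wdr38 opposite Rpl35, and 1810049J17Rik opposite Golph3, at 1907 to 4308 TPM. Within the mitochondrial genome, mt-Nd6, a subunit of respiratory complex I and the only protein gene on its strand, took 1.45% ± 0.206 of all counts (SD, n = 4) while all mitochondrially encoded genes took 1.91% ± 0.232. The 9 minus-strand mitochondrial genes, with 6.9% of the exonic length, held 83.6%, 75.6%, 83.0% and 77.7% of the mitochondrial counts in replicates 1 to 4.

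Genes with opposite-strand exons made up 16.2% of genes and 26.2% of exonic length, and held 90.3% ± 3.95 of the counts (SD, n = 4). The share was 90.74% in replicate 1 (Wilson 95% interval 90.7 to 90.78), 84.81% in replicate 2 (83.79 to 85.78), 94.22% in replicate 3 (94.19 to 94.25) and 91.33% in replicate 4 (91.29 to 91.37). All 50 genes with the highest mean CPM belonged to this class. Of 103 pairs in which a gene lay inside the exons of a protein-coding gene on the other strand, 100 had the lower count per base in the protein-coding gene in each of replicates 1, 3 and 4. Its median density was 0.22%, 0.11% and 0.21% of that of the gene inside it. The exceptions were Tbp around Pdcd2, Slc25a35 around Rangrf, and Gm5148 around Rps23-ps1, in which the outer gene was higher. Antisense or lincRNA biotypes took 31.0% ± 2.33 of the counts, nuclear protein-coding genes 50.9% ± 3.23 and ribosomal protein genes 0.921% ± 0.602. In the tests that follow, a gene's value is the count on its annotated strand. Fragments on the other strand of its locus were counted only where another gene is annotated there. A level, a lead within a list or a missing count below is thus a statement on that strand, and need not hold for the gene's RNA.

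**Figure D1:**
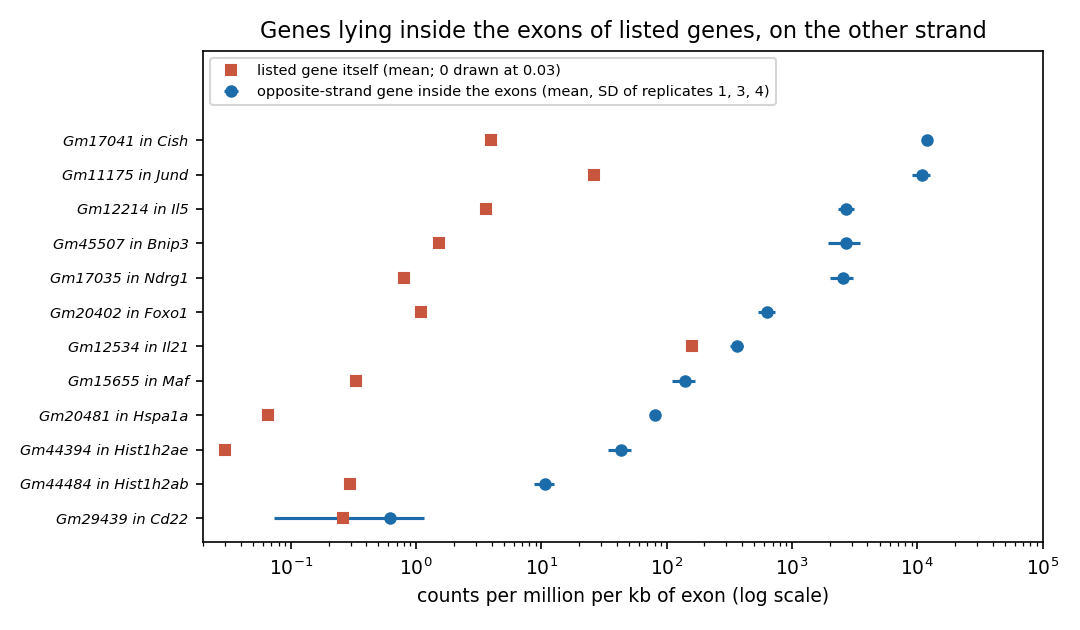
CPM per kb of exon, on a log scale, of genes with a count that lie inside the exons of listed genes on the other strand (circles, mean and SD of replicates 1, 3 and 4) and of the listed genes themselves (squares, mean). Gm17041 inside Cish is highest at 12040, while Cish itself is at 3.97, and Gm12214 inside Il5 is at 2713 against 3.63.

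**Figure D2:**
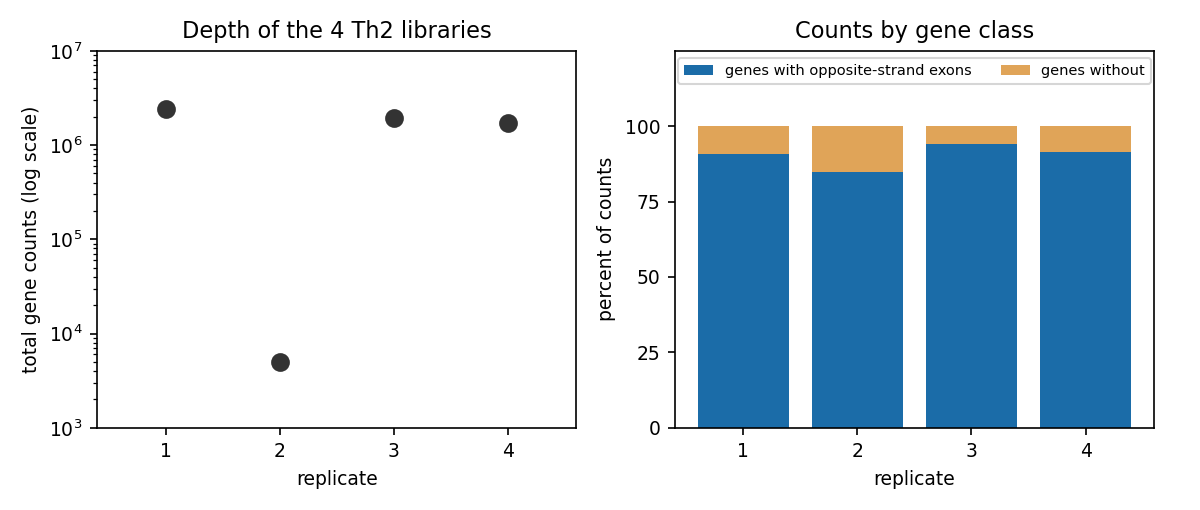
The left panel plots the total gene counts of each of the 4 Th2 libraries on a log scale, and the right panel the percent of counts in genes with and without opposite-strand exons. Replicate 2 sits at 5016 counts, and genes with opposite-strand exons hold 84.81% to 94.22% of the counts.

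The helper-subset lists were compared within each library, since the labels name the cells Th2. Cytokine genes of the Th2 list had counts on their annotated strand. Il13 stood at 65.7 ± 41.3 TPM (SD, n = 3, replicates 1, 3 and 4) and Il4 at 40 ± 7.95 TPM, 2 cytokines that drive IgE switching and mucus production. Ccr4, a homing receptor of Th2 cells, stood at 14.0 ± 7.11 TPM, and Gata3, the lineage-defining transcription factor, at 6.87 ± 3.42 TPM. Ifng and Il17a, the signature cytokines of Th1 and Th17 cells, had no count in any library, and Tbx21, the Th1 master regulator, had 5, 0, 1 and 2 counts in replicates 1 to 4.

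The Th2 list exceeded the Th1 list by 1.28 ± 0.65 and the Th17 list by 1.38 ± 0.73 on the log2(TPM + 1) scale (SD, n = 4), higher in 4 of 4 libraries for both, though in replicate 2 through 1 count of Gfi1 alone. Its difference from the regulatory T cell (Treg) list was 0.10 ± 0.33, higher in 2 of 4, and from the follicular helper (Tfh) list 0.14 ± 0.74, higher in 3 of 4. The exact sign-flip permutation p was 0.13 for the first 2 contrasts, the smallest that 4 libraries allow, and 0.625 and 0.875 for the others. Benjamini-Hochberg adjustment over the 4 contrasts gave 0.25, 0.25, 0.833 and 0.875, so none passed. Without replicate 2 the differences were 1.59 ± 0.18, 1.73 ± 0.26, 0.20 ± 0.32 and 0.50 ± 0.29 (n = 3), with exact p of 0.25 for all but Treg, at 0.5. Among members without opposite-strand exons they were 1.79 ± 0.24, 2.01 ± 0.30, 0.54 ± 0.33 and 0.87 ± 0.16 without replicate 2, an alternative chosen after the data were seen. Among members at 1 TPM or more in at least 1 library, a setting fixed in advance, they were 1.246, 1.263, −0.545 and −0.363 with 4 libraries, so the Treg and Tfh differences turned.

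Set against 1 TPM with limma, 14 of 20 Th2 list members lay above and 1 below without replicate 2, and 14 above and 2 below when adjusted over the list alone. With 4 libraries 1 lay above (Gfi1, a repressor that sustains Th2 growth) and 2 below. Il5, Il13 and Il4 lie together on chromosome 11, Il4 at 53602982 to 53618669, Il13 at 53631324 to 53634702 and Il5 at 53720794 to 53725106. Il5, the eosinophil growth factor, was at 5.20 ± 1.62 TPM. Besides Il4, Il5, Il13, Ccr4 and Gata3, the members above were Ptgdr2, the prostaglandin D2 receptor of Th2 cells, Gfi1, Il3, Il10, Il24, Ccr8, Il4ra, Pparg and Stat6, the transcription factor downstream of the interleukin 4 receptor. These 9 stood at 3.33 to 30.2 TPM. Bhlhe41 was the member below, at 0.187 ± 0.224 TPM. Nfil3, Areg, Il17rb, Maf and Il1rl1, the interleukin 33 receptor, were undecided at 0.216 to 4.25 TPM. Of the members above 1 TPM, Ptgdr2 has exons opposite Ccdc86, Gata3 opposite Gm13256, Stat6 opposite Nab2 and Il5 opposite Gm12214. Gfi1 has exons opposite A430072P03Rik and Il4ra opposite Gm44876. Ccdc86 had 14, 0, 2 and 5 counts in replicates 1 to 4. The counts of these members need not come from their own RNA.

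Members of the other helper lists lay above 1 TPM in 3 of 18 (Th1), 3 of 12 (Th17), 6 of 12 (Treg) and 4 of 10 (Tfh) cases without replicate 2, the same numbers when adjusted over the list alone. With 4 libraries limma put 0, 0, 1 and 2 above, also when adjusted over the list alone, and 0, 0, 2 and 2 at an unadjusted p under 0.05. In the Th1 list the 3 were Lta, Il18r1 and Il12rb2, the inducible interleukin 12 receptor chain, at 5.98 ± 1.02 TPM. In the Th17 list they included Tmem176a and Il23r, the interleukin 23 receptor, at 4.14 ± 1.27 TPM. The exons of Il12rb2 overlap Serbp1 on the other strand and those of Tmem176a overlap Tmem176b, so their counts need not come from their own RNA. Foxp3, the Treg master regulator, stood at 91.2 ± 0.698 TPM with 605, 1, 496 and 435 counts. Its exons overlap those of Ccdc22 on the other strand by 590 bp, and Ccdc22 had 3, 0, 5 and 5 counts. The Foxp3 counts therefore need not come from Foxp3 RNA. Il2ra, the high-affinity interleukin 2 receptor chain, was at 57.1 ± 31.4 TPM, Ctla4, an inhibitory receptor, at 26.4 ± 14.3 TPM and Nrp1 at 9.85 ± 0.751 TPM. Ikzf2 and Ikzf4, transcription factors of Treg cells, were below 1 TPM. Il21, the Tfh cytokine, reached 227 ± 79.4 TPM, with 1574, 1, 2297 and 1143 counts, and holds Gm12534 on the other strand. Btla was at 28.7 ± 1.94 TPM, while Bcl6, the Tfh master regulator, was below 1 TPM with 3 counts in all.

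**Figure D3:**
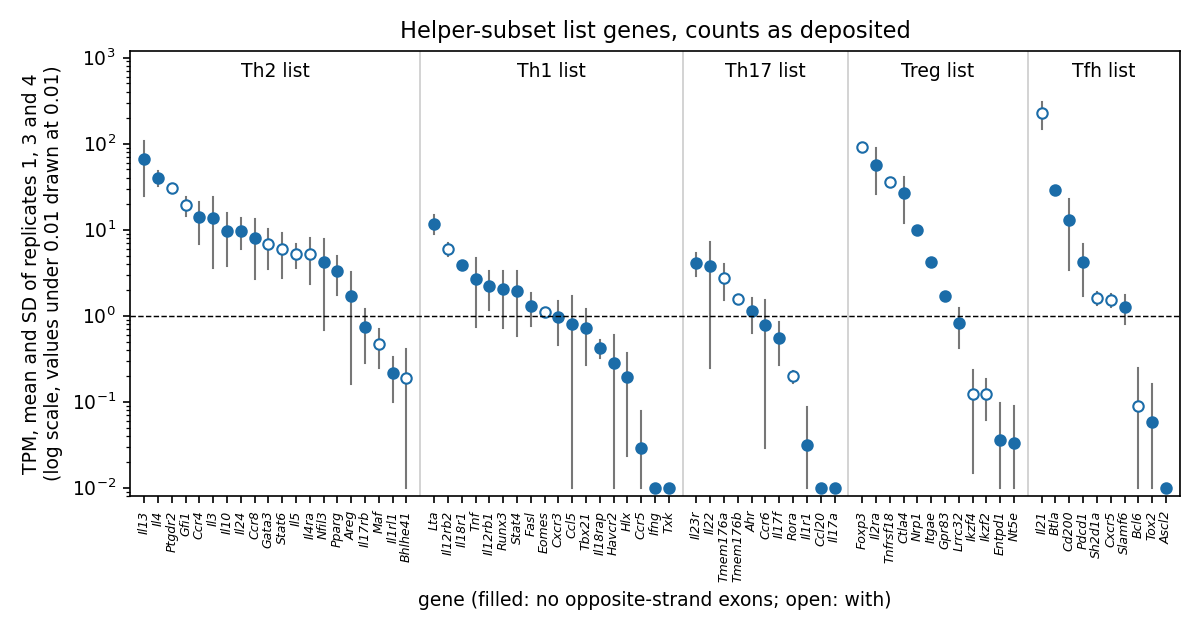
TPM of members of the 5 helper lists, as mean and SD of replicates 1, 3 and 4 on a log scale, with filled points for genes without opposite-strand exons and open points for genes with them. Il13 at 65.7 and Il4 at 40 TPM lead the Th2 list, and Il21 at 227 and Foxp3 at 91.2 TPM, which lead the Tfh and Treg lists, are genes with opposite-strand exons.

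Preset pairs set the counts of lineage genes on their annotated strands against each other, which need not have the direction of the RNAs, and the exons of Gata3, Foxp3, Bcl6, Il5 and Stat6 overlap genes on the other strand. Pooled over replicates 1, 3 and 4 and corrected for length, Gata3 was 9.15 times Tbx21 (95% counting interval 4.49 to 21.7), 65.7 times Bcl6 (21.9 to 323) and 0.0764 times Foxp3 (0.0627 to 0.0922). Il4 was at least 71.8-fold higher than Ifng and at least 64.9-fold higher than Il17a, taking a floor of 3 counts over the 3 libraries for the genes without a count. Il13 was 12.8 times Il5 (9.01 to 18.8). The ratio of Il4 to Il13 was 0.586 (0.49 to 0.699) in the pooled counts but went both ways, at −1.60, 1.34 and −1.01 log2 in replicates 1, 3 and 4. Cd4, the co-receptor of helper T cells, had 239 counts and Cd8a, that of cytotoxic T cells, had 1, which is below the floor of 3 counts. Stat6 was 3.13 times Stat4, the Th1 signal transducer (2.10 to 4.79). Over 4 libraries the mean log2 ratio of Gata3 to Foxp3 was −5.30 ± 2.95, with an exact sign-flip p of 0.13, the smallest possible. In replicate 2 this ratio came from 1 count of Foxp3, and without it the mean was −3.87 ± 0.895 (n = 3). For Cd4 to Cd8a the p was also 0.13, with a size set by the pseudocount. The other pairs given here had no count in either gene in replicate 2, so their p of 0.25 or more says nothing on these ratios.

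Over all genes, the limma test put 1999 of 17746 genes above 1 TPM and 4798 below with 4 libraries, and 6170 above and 2854 below of 17740 without replicate 2. The T cell list lay above 1 TPM in 16 of 16 members without replicate 2 (6 with 4 libraries), led by Cd247, the zeta chain of the T cell receptor complex, at 97.4 ± 8.81 TPM, whose exons overlap Pou2f1, and including Cd2, Cd5, Trac and Cd4. The activated T cell list lay above in 12 of 16, with Irf4, a transcription factor induced by receptor signalling, at 102 ± 10.5 TPM and Batf, its partner, at 36.8 ± 19.5 TPM. The resting list lay above in 6 of 14, led by Dapl1 at 14.7 ± 2.54 and Tcf7 at 9.20 ± 3.68 TPM, whereas Klf2, a quiescence factor, was below. With 4 libraries 3 activated and 0 resting members lay above. Each of these counts was the same when adjusted over the list alone.

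Genes of growth and metabolism were set against the same level, and where no other number is given the count was the same when adjusted over the list alone. Without replicate 2, 12 of 18 proliferation genes lay above 1 TPM, with Mki67, a marker of cycling cells, at 12 ± 5.22 TPM, Pcna at 18.9 ± 8.22 TPM and Ccna2 at 137 ± 3.39 TPM, whose exons overlap Exosc9. Of the glycolytic enzymes 13 of 14 lay above, led by Pfkp at 63.1 ± 2.83 TPM, Ldha at 47.9 ± 25.4 TPM and Pkm at 42.0 ± 18.1 TPM, and of the oxidative phosphorylation genes 12 of 13, led by Cox6c at 43.3 ± 4.10 TPM. Cholesterol synthesis genes lay above in 6 of 14, led by Fdft1 at 17.0 ± 1.66 TPM. The unfolded protein response list lay above in 7 of 10 (8 adjusted over the list alone), with Ddit3 at 111 ± 10.4 TPM and the chaperones Calr at 68.7 ± 31.6 TPM and Hspa5 at 26.6 ± 13.5 TPM. Cytokine feedback genes lay above in 11 of 13 (12 adjusted over the list alone), led by Pim1, a kinase induced by STAT5, at 16.6 ± 7.54 TPM. The p53 targets lay above in 6 of 9, led by Ccng1 at 11.3 ± 4.87 TPM, and the immediate early and heat shock list in 5 of 12, led by Junb at 129 ± 48.4 TPM. The interferon response list lay above in 2 of 15, Usp18 and Bst2, and the hypoxia list in 2 of 11, Egln3 and Bnip3l (1 adjusted over the list alone). With 4 libraries far fewer lay above, 2 proliferation, 5 glycolysis, 1 oxidative phosphorylation, 0 cholesterol, 3 unfolded protein response (4 adjusted over the list alone), 1 cytokine feedback, 1 p53, 2 immediate early, 0 interferon and 0 hypoxia genes. At an unadjusted p under 0.05 the lists at 0 had 1 cholesterol gene and none of the others. Besides Ccna2, the genes Pfkp, Cox6c, Fdft1, Ddit3, Pim1, Junb and Usp18 of this paragraph have opposite-strand exons, so their counts need not come from their own RNA.

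Markers of other cell types often had no count on their annotated strand, which does not show that their RNA was absent. Of all 21751 nuclear protein-coding genes, 12755 had a count in any library. No count in replicates 1, 3 and 4 was found for 4 of 10 cytotoxic genes, 6 of 8 natural killer genes, 4 of 5 gamma delta T cell genes, 5 of 10 B cell genes, 10 of 14 myeloid genes and 4 of 9 dendritic cell genes. The same held for 7 of 11 mast cell, basophil and eosinophil genes, 6 of 9 erythroid and platelet genes, 7 of 9 stromal and epithelial genes and 3 of 5 thymocyte genes. Members above 1 TPM without replicate 2 were Ctsw at 5.05 ± 1.64, Cd79a at 5.80 ± 3.90, Csf1r at 140 ± 9.75, Cd68 at 3.77 ± 0.273, H2-Ab1 at 9.34 ± 1.33, Cd74 at 3.51 ± 1.63, Alas2 at 9.69 ± 0.852 and Pecam1 at 8.82 ± 1.64 TPM. Csf1r, the receptor of the macrophage growth factor, has exons opposite Hmgxb3, which had 16, 0, 6 and 9 counts in replicates 1 to 4. Alas2, a heme synthesis enzyme, has exons opposite Apex2. Their counts need not come from their own RNA. Of 12 replication-dependent histone genes 6 had no count, and of 11 small RNAs without poly(A) tails 9 had none. In limma 0 members of either list lay above 1 TPM, with 4 libraries or without replicate 2, and 0 at an unadjusted p under 0.05.

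The replicates were then compared with each other. Across all 50600 genes the Pearson correlation of log2(TPM + 1) was 0.960, 0.971 and 0.957 among replicates 1, 3 and 4 (Spearman 0.857, 0.881 and 0.855) and 0.639 to 0.642 between these and replicate 2 (Spearman 0.382 to 0.387). These 6 pairs were described, not tested, as genes are not replicates. To see whether a library had been deposited more than once, counts were compared pair by pair. Chi-square over degrees of freedom was 5.41 to 9.92 among replicates 1, 3 and 4 and 1.82 to 2.43 with replicate 2, so no pair agreed within sampling noise. The biological coefficient of variation was 0.276, and 0.169 without replicate 3, which moves it by over 1.5 times. It was 0.174 in genes with opposite-strand exons and 0.329 in genes without.

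Variation between libraries beyond the trend was found by edgeR in 5 of 5969 genes. Tsix, the antisense regulator of Xist, had 3223, 2, 1 and 3 counts (adjusted p = 4.24e-59), Gm27520 had 394 counts in replicate 1 and none elsewhere (2.44e-29), and Xist itself had 80, 0, 6 and 2 (5.30e-04). Rps6ka3, a kinase gene of the X chromosome, had 27, 1, 0 and 33 (0.00259) and Gm42418, which overlaps a ribosomal RNA gene, had 160, 4, 50 and 245 (0.0140). Below the threshold followed Far1, Il2ra, Gm37804, Ddx1 and Rabgap1l, with adjusted p of 0.0794 to 0.119. Leaving out replicate 1, 2 or 4 left 2 genes each, and leaving out replicate 3 gave 6.

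Genes standing apart in a single library were fewest in replicates 1 and 4. In replicate 1 edgeR called 3 genes, all higher, the X-linked Tsix (log2 fold change 9.46, SE 0.72, adjusted p = 3.49e-35), Gm27520 (10.90, SE 1.03, adjusted p = 2.09e-22) and Xist (3.80, SE 0.75, adjusted p = 7.84e-04). DESeq2 called 0 there, with 1 gene at an unadjusted p under 0.05 against 71 in edgeR, and the count was 910 without replicate 4 and 14 without replicate 3. In replicate 4 edgeR called 0 genes, with 48 at an unadjusted p under 0.05, and DESeq2 called 0, with 2. Without replicate 1 edgeR called 608 genes in replicate 4, and 15 without replicate 3. In replicate 2 it called 61 genes, all lower, among them Nudt6, Gm45205, Gm37422, A830012C17Rik and Dnah17, at 0 counts there and 1353 to 3751 in the others. Without replicate 1 no gene was called in replicate 2 by edgeR, with 428 at an unadjusted p under 0.05, and without replicate 3 or 4 the counts were 98 and 99. DESeq2 called 37 of 2729 genes there with 4 libraries, 9 higher and 28 lower.

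Replicate 3 stood apart in 919 of 5969 genes in edgeR, 56 higher and 863 lower, and most of the list genes among them were lower. In the simulation this test gave a larger share of false calls than its adjusted threshold allows, so the same may hold for these calls. The largest changes were those of Rps6ka3 (log2 fold change −7.50, SE 1.11), Far1, an ether lipid enzyme gene (−4.67, SE 0.77), Usp4 (−4.04, SE 0.75), Exosc10 (−4.02, SE 0.75) and Dicer1, the microRNA-processing nuclease (−4.00, SE 0.75). Their adjusted p in edgeR lay between 3.00e-07 and 2.83e-04. Higher were Gm37804 at 2.41 (SE 0.38), Ddx1, an RNA helicase gene, at 2.06 (SE 0.36) and Il10, an anti-inflammatory cytokine, at 1.31 (SE 0.41, adjusted p = 0.0171). In the T cell list 10 of 14 tested members fell (11 adjusted over the list alone), such as Cd4 at −1.24 (SE 0.41, adjusted p = 0.0243) and Cd2 at −1.57 (SE 0.43, adjusted p = 0.00608). In the Th2 list 6 of 12 fell and 1 rose, the same when adjusted over the list alone, with Il13 at −2.06 (SE 0.44, adjusted p = 4.19e-04) and Gata3 at −1.40 (SE 0.47, adjusted p = 0.0243).

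Further lists had members that fell in replicate 3. These were 7 of 14 activated T cell genes (9 adjusted over the list alone), with Cd44, an activation marker, at −3.04 and Il2ra at −1.59, and 7 of 11 proliferation genes (8 adjusted over the list alone), with Mcm3, a replication helicase subunit, at −2.83 and Top2a at −1.73. Also lower were 7 of 12 glycolysis genes (8 adjusted over the list alone), with Eno1 at −2.19 and Ldha at −1.54, and 5 of 10 oxidative phosphorylation genes (8 adjusted over the list alone), with Cycs at −2.30. The same held for 4 of 7 cholesterol genes, 4 of 10 cytokine feedback genes, 3 of 6 unfolded protein response genes (4 adjusted over the list alone), 1 of 2 hypoxia genes (2 adjusted over the list alone) and 1 of 3 p53 targets (2 adjusted over the list alone). Members of the other helper lists fell in 2 of 6 Treg (Il2ra and Ctla4), 1 of 4 Tfh (Cd200) and 1 of 5 Th1 cases (Runx3), the same when adjusted over the list alone except that Il21 then rose. Genes without opposite-strand exons held 5.78% of the counts of replicate 3, against 9.26% and 8.67% in replicates 1 and 4. Their median log2 change without replicate 2 was −0.82, against 0.12 in genes with opposite-strand exons. When the classes were scaled separately in replicates 1, 3 and 4, a choice made after the data were seen, edgeR called 550 genes, 308 higher and 242 lower. The T cell list then had 1 lower member, the proliferation list 1, the glycolysis list 6 and the Th2 list 4 lower and 2 higher. The activated T cell, cholesterol and cytokine feedback lists had 2 lower members each, the oxidative phosphorylation, Treg and Tfh lists 1 each, and the unfolded protein response, hypoxia, p53 and Th1 lists 0, while 2 Tfh, 1 Treg and 1 activated T cell member were higher. DESeq2 with 4 libraries called 0 genes in replicate 3, with 20 at an unadjusted p under 0.05.

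The deviation of whole lists from the mean of the libraries was set against random lists. With 4 libraries, 1 of 64 tests passed, the T cell list in replicate 3, whose mean log2 CPM deviated by −0.16 while random lists had a median of 0.79 (percentile 0.0, adjusted p = 0.0128). By median deviation, a setting fixed in advance, it did not pass (0.19, adjusted p = 0.205), and with DESeq2 size factors the proliferation list passed beside it. As a description of replicates 1, 3 and 4, with random lists matched on strand class too and chosen after the data were seen, 4 of the 17 lists tested were lower in replicate 3. These were the T cell (−0.79, adjusted p = 0.0136), proliferation (−0.82, adjusted p = 0.0238), glycolysis (−0.65, adjusted p = 0.0136) and cholesterol lists (−0.87, adjusted p = 0.0499). As the deviations of a list sum to 0 over the 3 libraries, the T cell, glycolysis and cholesterol lists called higher in replicate 1 or 4 mirror these. The immediate early list in replicate 1 (0.49, adjusted p = 0.0277) and the activated T cell list in replicate 4 (0.54, adjusted p = 0.0102) were higher without being called lower in replicate 3. The p-values come from random lists of genes and describe these libraries, not a condition.

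Sex-linked genes separated the replicates. Replicate 1 had 3223 counts of Tsix, on the X chromosome at 103431517 to 103484957, and 80 of Xist, the RNA that silences an X chromosome in female cells. Tsix has 1943 bp of exon opposite Xist, and Gm27520 lies inside Xist, so these counts need not tell the RNAs apart. Replicate 1 had 1 count in genes of the Y chromosome. Replicates 3 and 4 had 1 and 3 counts of Tsix, 6 and 2 of Xist, and 10 and 39 of Y-linked genes. Of these, Ddx3y had 5 and 16 counts, Eif2s3y 4 and 15, Kdm5d 0 and 5 and Uty 1 and 3. Replicate 2 had 2 counts of Tsix and none of the Y chromosome. At the rate of replicate 1, 6.77 Tsix counts would be found at its depth (exact Poisson p of 2 or fewer, 0.0352), and at the rates of replicates 3 and 4 the exact Poisson p of 2 or more was 3.37e-06 and 3.83e-05. These p-values take each rate as known, though the rates of replicates 3 and 4 rest on 1 and 3 counts. They also leave out spread between libraries, and Tsix was named for its variation, so they describe and do not place replicate 2.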

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

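All tests of explanations in this part were chosen after the results had been seen. Each value was compared with the other 3 libraries by the gap to its nearest neighbour over the whole range, for 227 values, and a gap counted only when it exceeded the worth of 3 counts in the shallower library. The gap alone passes about 1 in 20 values by chance, and 11 values were flagged. The 3-count requirement lowers that rate by an amount not known here, and some genes were included because they had been called apart. The 11 are therefore described, not set against chance.

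Replicate 2 accounted for most of the values that lay far from the others. It had 2017 genes with a count, against 13995 to 15516 in the others. Mki67, the cycling marker, was at 797.4 CPM in replicate 2 against 43.0 to 108 CPM elsewhere, from 4 counts. Gm42418, which overlaps a ribosomal RNA gene, was at 797.4 CPM against 25.9 to 143 CPM, also from 4 counts. Gm17606 was at 1196 CPM in replicate 2 against 489.1 to 531.8 CPM. Gm20721, opposite Gnas, was at 11360 CPM in replicate 2 against 21360 to 21930 CPM, and Snx22, opposite Ppib, at 2990 CPM against 4715 to 5025 CPM. Nudt6, Gm45205, Gm37422 and A830012C17Rik were at 0 CPM in replicate 2 and at 782.2 to 1684 CPM in the others. In replicate 1, Xist stood at 33.5 CPM against 0 to 3.11 CPM.

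The first pattern weighed is the large share of counts in genes that lie opposite other genes. Reads without strand information would give both strands like counts, but the protein-coding gene of a pair held at most a median of 0.22% of the density of the gene inside it, which argues against it. Transcription of nuclear antisense genes cannot account for the mitochondrial part, where mt-Co1 reached at most 1.32% of mt-Nd6 per base. The candidate explanation that these values do not argue against is that fragments were counted on the strand opposite to the RNA. In 100 of 103 pairs the protein-coding gene was lower, and the headers name strand-specific alignments. Minus-strand mitochondrial genes, with 6.9% of the exonic length, held 83.6%, 83.0% and 77.7% of the mitochondrial counts in replicates 1, 3 and 4. It stays a candidate, as the other strand was not counted. Under it, a level given here need not be that of the named gene's RNA. The design holds a single group, so no biological explanation drawn from groups was tested for any pattern.

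The second pattern is the 919 genes apart in replicate 3, or 1051 without replicate 2, on which the scaling was tested. In the simulation the test of replicate 3 gave a larger share of false calls than its adjusted threshold allows, with and without replicate 2. The same may hold for these calls. Library size as the cause is argued against by the total of replicate 3, 1929880, which lies between those of replicates 1 and 4. For a lower share of counts in all genes without opposite-strand exons, the classes were scaled separately, which centres each class. In genes without them, 100% of the higher calls were left, their median log2 change going from 0.966 to 1.80 (SD 0.590). As the scaling raised the whole class, it could not end these calls, so the test is void for them. Of 672 lower calls 6.5% were left, but their median moved from −1.74 to −0.91 (SD 0.850) as the class median moved from −0.824 to 0.009, so calls ended through a shift common to the class. The test is void there, and the share cannot be told apart from changes of single genes. In genes with opposite-strand exons, 97.8% of the lower calls were left, and their median log2 change moved from −1.64 to −1.77 (SD 1.19). As the scaling lowered this whole class, it could hardly end these calls. The test is void for them, and their source stays open. Of 168 higher calls in that class 32.7% were left, their median going from 0.517 to 0.39 (SD 0.365) by the shift common to the class, so the test is void for them too.

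The third pattern is the opposite distribution of Tsix and Y-linked counts. A single animal behind all libraries, which the shared donor label would allow, is argued against by Tsix, which was 771 times higher in replicate 1 than in the higher of replicates 3 and 4. Cells from animals of both sexes stay open as a candidate explanation, with 49 Y-linked counts in replicates 3 and 4 against 1 in replicate 1 (exact Poisson rate test p = 5.18e-10). The rate test used the Y-linked counts that raised the pattern, so it restates the pattern and adds no support. Tsix has 1943 bp of exon opposite Xist, so which of both RNAs gave its counts is open. Sex was not collected, per the labels, so the label cannot settle it.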

How the results depend on the processing

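Tests and list contrasts within a strand class, scaling by class, and strict or median lists, deviance, list deviations and library correlations without replicate 2 were chosen after the data were seen. The other settings were fixed in advance. No paired analysis was possible because the labels give a single group. Deposited FPKM as an alternative was not run, as the files hold counts alone. Among main values under the settings fixed in advance 55 kept their direction and size, 34 moved and 5 reversed, and among those chosen later 15 kept them and 11 moved. Among gene pairs, shares of RNA classes and list deviations 215 and 74 did, while 22 of the later ones passed a threshold they had missed, and of the earlier ones 5 moved, 1 reversed, 1 passed (the proliferation list in replicate 3 with DESeq2 size factors) and 1 lost it (the T cell list in replicate 3 by median deviation). Unless the construction shows it, the cause was not tested.

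The Th2 list lay above the Th1 and Th17 lists under each alternative, with strict lists without replicate 2 moving the Th1 difference to 2.45. The Treg difference (0.10) was 0.47 with a pseudocount of 0.1, 0.55 for medians, 0.60 for strict lists, 0.54 for members without opposite-strand exons without replicate 2, 1.15 for strict lists and 0.74 for medians there. It turned to −0.54 with members at 1 TPM or more, and ranged from −0.001 without replicate 4 to 0.20 with each replicate left out. The Tfh difference (0.14) was 0.96 for medians, 1.29 for medians without replicate 2 and −0.36 with members at 1 TPM or more. It ranged from −0.043 without replicate 1 and −0.017 without replicate 4 to 0.50 with each left out. The log2 ratio of Il4 to Il13 (−0.32) ranged from −0.87 without replicate 3 to 0.11, its only turn, without replicate 1. As TPM the mitochondrial share was 6.12%, that of mt-Nd6 4.058%, that of nuclear protein-coding genes 23.381% and that of antisense or lincRNA biotypes 44.803%, which turned the order of the last 2, and that of other biotypes 25.699%. The ratio of Cd4 to Cd8a was 4.594 log2 with a pseudocount of 1.

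Variable genes (5) numbered 2 at a mean count of 50 or more, 17 by negative binomial deviance, 2539 by a Poisson chi-square, which ignores variation beyond counting, 20 within genes with opposite-strand exons, 0 in edgeR within genes without (43 at an unadjusted p under 0.05), 10 by deviance without replicate 2, and 2 to 6 with each replicate left out. Genes apart in replicate 1 (3) numbered 0 in DESeq2, 8 within genes with opposite-strand exons, and 2 to 910 with a replicate left out. For replicate 2 (61) the counts were 37 in DESeq2, 126 unfiltered and 0 to 99. For replicate 3 (919) they were 0 in DESeq2, 550 scaled by class, 215 within genes with opposite-strand exons (46 higher, 169 lower) and 671 to 1051. For replicate 4 (0) they were 3 unfiltered and 1 to 608. The 910 and 608 calls come from fits in which replicates 2 and 3 were the remaining libraries. Genes above 1 TPM (1999) numbered 1232 when TPM was rescaled to nuclear protein-coding genes and 1450 to 6170 with a replicate left out, highest without replicate 2. Genes below 1 TPM (4798) numbered 2858 below 0.5 TPM, 9055 below 5 TPM, 418 rescaled, 2 at a mean count of 10 or more, and 2509 to 2964. The numbers by strand class for genes apart in replicates 1 and 3 come from fits without replicate 2. They are therefore not like for like with the 4-library numbers beside them. Replicate 2, with 5016 counts, limits what 4 libraries can show.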

Other observations

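The test of RNA selection below was written before its result was seen, and the genes of the next paragraph were chosen after their values had been seen. Genes that lie inside the exons of listed genes on the other strand had far higher counts per base than the listed genes in most cases. Gm12214, inside the exons of Il5 on chromosome 11 at 53723953 to 53724618, had 2593, 1, 1927 and 2244 counts in replicates 1 to 4, or 2713 ± 385.1 CPM per kb of exon (SD, n = 3, replicates 1, 3 and 4), against 3.63 for Il5 itself. Gm17041, inside Cish, a feedback inhibitor induced by STAT5, stood at 12040 ± 310.9 and Gm11175, inside the AP-1 gene Jund, at 10860 ± 1839. Gm12534, inside Il21, stood at 364.5 ± 45.6 against 159.5 for Il21 itself, and Gm15655, inside Maf, a transcription factor that promotes Il4, at 138.8 ± 28.6.

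Further listed genes, again chosen after their values were seen, had the same arrangement. Gm45507 inside Bnip3, a mitophagy gene, stood at 2702 ± 770.7 and Gm17035 inside Ndrg1 at 2554 ± 535.3. Gm20402 inside Foxo1, a factor of resting T cells, stood at 629.9 ± 96.7. At the other end were Gm20481 inside the heat shock gene Hspa1a at 80.0 ± 2.39, Gm44394 inside the histone gene Hist1h2ae at 43.1 ± 8.86, and Gm29439 inside the B cell gene Cd22 at 0.614 ± 0.540 against 0.261 for Cd22. Mir3620 inside Alas2 had none against 6.79 for Alas2. Other opposite genes overlapped a listed gene in part. In replicates 1, 3 and 4, Gm13256 opposite Gata3 had 2593, 1824 and 1867 counts, Gm44876 opposite Il4ra 1523, 1518 and 1155, and Gm16008 opposite Tnfrsf18, a costimulatory receptor gene, 16097, 15816 and 11469. Gm33460 opposite Eomes, a Th1 and cytotoxic factor, had 3, 5 and 8, and Gm12462 opposite the B cell factor Pax5 and Gm11505 opposite the myeloid gene Mpo had none.

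The labels name total RNA while the protocol document's name speaks of poly(A) selection. Selection would leave histone and small RNAs low, and the median of the preset histone genes was at most 0.466 TPM, with Rn7sk, Rmrp and Rpph1 at 2.21 TPM or less. Protein-coding genes also held a median of 0.22% or less of the density of a gene inside their exons, so a low count on the annotated strand does not show that an RNA was scarce. The test is therefore void, and it cannot tell total from poly(A)-selected RNA. Genes of the rRNA biotype, looked at after the values were seen, held a mean of 4.71% of the counts without replicate 2. Among them CT010467.1, with exons opposite Gm42418, had the highest mean CPM of all genes, at 47063. What share either selection would leave was not tested, so the question stays open.

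The number of genes in replicate 2 was set against draws from the other libraries. It had 2017 genes with a count, against a median of 1674 (central 95% of draws 1629 to 1724) in 1000 draws of as many counts from the other 3 libraries, and 6 of its counts lay in genes without a count in those. These draws hold no spread between libraries, and the others thinned singly to its depth gave 1708, 1560 and 1675, a wider range, so this difference is described, not tested. Its share in genes without opposite-strand exons was 15.19% (Wilson 95% interval 14.22 to 16.21), the highest of the 4.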
